A study of Mus musculus with 12 samples.

How the data were processed

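RNA sequencing libraries were made from mouse hippocampal neural stem cells (HpNSCs), cells of the hippocampus that renew themselves in culture and can form neurons and glia. Per the labels, the cells were expanded with the growth factors EGF and FGF2 and were then treated for 3 days in N2 medium with FGF2. The treatments were dexamethasone (Dex, a synthetic glucocorticoid that activates the glucocorticoid receptor) at 1e-06 M, bone morphogenetic protein 4 (BMP4, a ligand of the BMP receptors) at 20 ng/mL, both together, or neither. Each of the 4 groups held 3 libraries. Per the labels, total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra II RNA kit. The labels do not say whether the libraries were strand-specific, nor whether the replicates were separate cultures, so the 3 libraries of a group may be technical replicates.

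The processing notes deposited by the authors name Trim Galore 0.6.7, HISAT2 2.1.0, StringTie 1.3.6, DESeq2 without a version and R 3.6.1, with the genome build mm10. The notes do not give the role or the order of the tools. For each library the authors deposited a table with 115220 transcripts of 47729 genes, in the layout that StringTie writes. Per the file headers, each table holds FPKM (fragments per kilobase of transcript, scaled to the number of aligned fragments). Per the file headers, each table also holds the mean coverage per base of each transcript, a signal that the authors did not scale between libraries. Within a library coverage was a fixed multiple of FPKM, between 4.58 and 5.73 depending on the library. Read counts were not analysed here. Coverage times transcript length gave 4.20 to 5.23 Gb of aligned bases per library, which is the depth behind the values. Depth in reads is unknown, so no counting intervals are given and the spread between replicates is the only error. Of the gene identifiers, 47224 of 47729 (98.9%) were found in GENCODE M21. Coordinates are those of the deposited tables on mm10.

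The FPKM values of a gene's transcripts were summed and log2-transformed after adding 1. The 13804 genes with an FPKM of at least 1 in at least 3 of the 12 libraries were tested with limma 3.58.1 in R 4.3.3, with the data.table package (1.17.8) for reading files. A single model with a mean for each of the 4 groups was fitted to all 12 libraries, followed by eBayes with trend and robust settings. Fold changes are differences of log2(FPKM + 1), given with the standard error (SE) of the model. The tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes of a comparison, with a threshold of 0.05. The 7 comparisons were each treated group against untreated, the groups labelled Dex and BMP4 against each other, the combination against each single treatment, and the interaction. The interaction is the change in the combination minus the sum of the changes in the single treatments, on the log2 scale. DESeq2 and edgeR were not used because they need counts. Tables were prepared and figures drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

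Before the data were examined, 31 gene lists were fixed, covering the expected pathways of both treatments, the cell cycle, metabolism and markers of the cell types such a culture could hold. The 29 lists with at least 3 tested members were compared with the other genes by camera from limma, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison. The same test with an estimated correlation and the test fry were run beside it. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Lists share members: 6 genes stand in both the quiescence and the astrocyte list, 4 in both the BMP-SMAD and the Ascl1 regulator list, and 3 in both the progenitor and the Notch list. Pdk4 stands in both the fatty acid oxidation and the glucocorticoid target list. The named genes also follow a rule fixed before the data were examined. It takes Ascl1, and for each comparison between single groups and untreated and between the single treatments the 8 largest rises and 8 largest falls past the threshold. These had no overlap between the replicates of the groups and a mean FPKM of at least 5 in the higher group, and predicted gene models and Y chromosome genes were left out. For the interaction the rule takes 4 genes in each direction with a mean FPKM of at least 5 in some group, and from each list described the members with the smallest adjusted p.

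The labels were checked first, because the names of the deposited files of the groups labelled Dex and BMP4 read the opposite way from their labels. The means of 4 glucocorticoid targets (Fkbp5, Tsc22d3, Zbtb16 and Sgk1) and of 4 BMP targets (Id1, Id2, Id3 and Smad6) were compared between groups with an exact permutation test, two-sided. With 3 libraries against 3, this test cannot give a p under 0.1. The groups were kept as labelled whatever this check showed, and "labelled Dex" and "labelled BMP4" are written throughout for that reason. The untreated group, the combination and the interaction do not depend on which single-treatment label is right.

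The procedure was tested on simulated data at the size of the comparison of Dex with untreated. Changes were added only to genes with a mean log2(FPKM + 1) over 2, so recovery below that level was not measured. Of the genes given a change of 0.5, 1 or 2 on the log2 scale, 66.7%, 89.6% and 100% were called, with 6 false calls. Each gene was drawn with the same spread in all groups. Libraries that stand apart from their group, as in untreated and labelled Dex, were thus not represented. The false calls therefore do not measure those of the real comparison. In the simulated comparison of BMP4 with untreated, to which no change was added, 0 genes and 0 of the 29 lists were called, with genes drawn independently of each other.

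The alternatives fixed before the data were examined were the replicate number as a block, pseudocounts of 0.1 and 5, no filter on low values, a mean FPKM of at least 5, and rescaling each library to the same sum. Further ones were median-of-ratios scaling, quantile normalization, eBayes without trend and robust settings, array weights, and limma-voom on fragments estimated from coverage with an assumed fragment length of 150 bp. The most abundant transcript in place of the sum, only the groups compared in the model, and leaving out each library in turn were also tried. Others were added after seeing the data. Untreated replicate 1 and Dex replicate 1 were left out together because they stood apart from their groups, and a trend of the values on transcript length was removed from each library. The overlap and the label check were also recomputed under the alternatives written for the other results. The main model has no block, because the labels give the replicates only a number. No library was left out of the main model. Results of DESeq2 were not used here.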

Results

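Gene expression was measured by RNA sequencing in 12 libraries of mouse HpNSCs after 3 days with Dex at 1e-06 M, with BMP4 at 20 ng/mL, with both, or untreated, with n = 3 libraries in each of the 4 groups. The study asked how Dex and BMP4 differ in their effects on these cells, with the proneural transcription factor Ascl1 at its centre. Coverage per unit of FPKM, the measure of depth in these data, ranged from 4.58 to 5.73, which corresponds to 4.20 to 5.23 Gb of aligned bases per library. Between 13051 and 13242 genes per library reached an FPKM of 1. Mitochondrially encoded genes took 10.4% to 12.8% of the summed FPKM and the 10 most abundant genes 12.5% to 18.4%. Replicates of a group had Pearson correlations of 0.980 to 0.991 across the 13804 tested genes, which are not independent of each other. Median differences were taken over the 5863 genes with a mean FPKM of at least 10 in every group. Untreated replicate 1 differed from the other untreated libraries by a median of 0.170 and 0.189 on the log2 scale, against 0.0700 between those. Dex replicate 1 differed by 0.124 and 0.111, against 0.0710. Of 14 microglia markers only Hexb (highest group mean 18.8 FPKM) was tested, and the others had group means of at most 0.97 FPKM. Of 14 endothelial and mural markers only Rgs5 (43.3) and Tagln (1.26) were tested, and the others reached at most 0.76 FPKM.

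The mean of the 4 glucocorticoid targets fixed for the label check was raised in the libraries labelled BMP4 and not in those labelled Dex, and the mean of the 4 BMP targets showed the reverse. Fkbp5, a co-chaperone of the glucocorticoid receptor and one of its classic targets, had 8.54 ± 0.794 FPKM (SD, n = 3) in untreated libraries, 5.44 ± 0.662 in those labelled Dex, 127 ± 2.68 in those labelled BMP4 and 168 ± 6.16 in the combination. Tsc22d3 (1.29, SE 0.10, adjusted p = 3.95e-06) and Zbtb16 (1.92, SE 0.09, adjusted p = 6.19e-08) also rose in the libraries labelled BMP4. Sgk1 rose by 0.38 there (SE 0.10, adjusted p = 0.0121), a call that was lost without BMP4 replicate 2 (adjusted p = 0.0514) and with its most abundant transcript only (0.61, adjusted p = 0.401). The inhibitors of differentiation Id1, Id2 and Id3, direct SMAD targets, rose by 1.22, 1.08 and 1.10 in the libraries labelled Dex. The fourth BMP target, Smad6, stayed below the filter in all groups and was not tested singly.

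**Figure D1:**
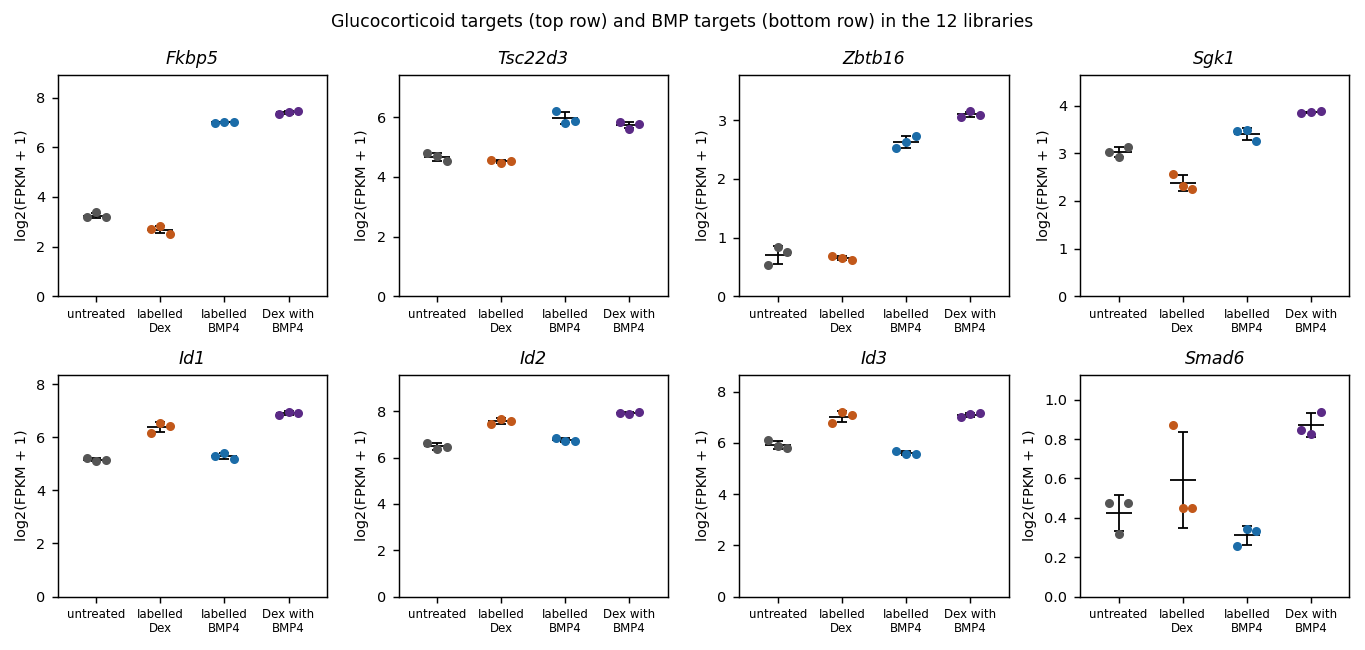
Expression of 4 glucocorticoid targets (top row) and 4 BMP targets (bottom row) as log2(FPKM + 1) in each of the 12 libraries, by labelled group; points are libraries, and bars show the mean and SD of the 3 libraries of a group. All 4 glucocorticoid targets lie higher in the libraries labelled BMP4 than in those labelled Dex, and Id1, Id2 and Id3 lie higher in those labelled Dex.

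The mean log2 value of the 4 glucocorticoid targets was 2.91 ± 0.038 (SD, n = 3) in untreated, 2.56 ± 0.078 in labelled Dex, 4.75 ± 0.035 in labelled BMP4 and 5.03 ± 0.02 in combination libraries. The mean of the 4 BMP targets was 4.50 ± 0.098, 5.39 ± 0.079, 4.49 ± 0.04 and 5.70 ± 0.048 in the same order. The glucocorticoid mean was lower by -2.19 (SE 0.049) in the libraries labelled Dex than in those labelled BMP4, and the BMP mean was higher by 0.90 (SE 0.051), each beyond the spread between replicates. Both differences had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The difference of labelled BMP4 from untreated in the BMP mean was -0.01 (SE 0.061, exact permutation p = 1). The single-treatment groups are therefore named by their labels throughout, and the direction of each comparison that involves them holds for the labels as deposited.

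The libraries labelled Dex were compared with untreated. Because of the label check, their changes are not credited to the glucocorticoid. The libraries labelled Dex had more transcripts of BMP targets, of astrocytes and of quiescent stem cells, and fewer of the oligodendrocyte lineage, cholesterol synthesis and the cell cycle. Sparcl1, a secreted matrix-associated protein of astrocytes and quiescent stem cells, went from 376 ± 13.8 FPKM (SD, n = 3) in untreated to 1162 ± 39.2 (log2 fold change 1.63, SE 0.05, adjusted p = 3.37e-08). Gpr17, a receptor of committed oligodendrocyte precursors, went from 17.6 ± 1.71 to 2.62 ± 0.410 FPKM (-2.36, SE 0.11, adjusted p = 4.8e-07). Sparcl1 (ENSMUSG00000029309) lies on chromosome 5 from 104079111 to 104113733 and Gpr17 (ENSMUSG00000052229) on chromosome 18 from 31942997 to 31949636 in mm10.

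Of the 13804 genes tested, 3553 changed in the libraries labelled Dex, 1318 higher and 2235 lower. At least a 2-fold change was seen for 145 of them, 72 higher and 73 lower, a count that depended on the pseudocount (351 with 0.1 and 37 with 5). The surplus of lower genes depended on the scaling, with 1639 higher and 1640 lower under median-of-ratios scaling, 1662 and 1719 under quantile normalization and 1475 and 1465 after rescaling the libraries to the same sum. Besides Sparcl1, the largest rises were those of Gas7 (1.77), Efemp1, an extracellular matrix protein (1.65), Ass1, argininosuccinate synthase (1.64), Abca1, a cholesterol efflux transporter (1.63), Atoh8, a transcription factor (1.58), and Siah3 (1.57). Kcnn2, a calcium-activated potassium channel, rose by 1.78 over its summed transcripts, but its most abundant transcript had -0.58 (adjusted p = 0.559). Besides Gpr17, the largest falls were those of C1ql1 (-1.88), Rph3a (-1.69), the lysophospholipid transporter Mfsd2a (-1.67), Tub (-1.60), Lims2 (-1.57), the protein kinase Prkcq (-1.54) and Tagln2 (-1.52). Adjusted p for these 16 genes ranged from 3.37e-08 to 7.26e-05, and the replicates of the groups did not overlap. Exons of Lims2 overlap those of Gpr17 on the opposite strand over 6.1% of their length, and whether its fall is separate from that of Gpr17 was not tested. With only these groups in the model the count was 1735. The main model shares its estimate of the spread across all groups, and both groups here hold a replicate that stands apart. Its adjusted p for this comparison can therefore be too small.

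Of 13 BMP-SMAD targets tested, 9 were higher, 0 lower and 4 did not pass in the libraries labelled Dex, and the counts were the same when adjusted over the list alone (mean 0.65, adjusted p = 5.37e-09, p = 0.00789 with an estimated correlation). Atoh8 rose by 1.58 (SE 0.11) and Id1 by 1.22 (SE 0.09). Of 22 glucocorticoid receptor targets, 5 were higher, 2 lower and 15 did not pass, and 6 were higher and 2 lower adjusted over the list alone. Their mean was 0.12 and the list was not called (adjusted p = 0.103), although it was without Dex replicate 1 (0.16, adjusted p = 0.0324). The members with the smallest adjusted p were Fkbp5 (-0.57, adjusted p = 0.000575) and Sgk1 (-0.65, adjusted p = 0.000801), both lower. The call for Sgk1, a kinase induced by corticosteroids, was lost with the most abundant transcript only (-0.59, adjusted p = 0.425).

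Quiescence genes of neural stem cells had 14 higher, 1 lower and 8 not passing of 23 in the libraries labelled Dex, the same adjusted over the list alone (mean 0.37, adjusted p = 6.61e-08, p = 0.00471 with an estimated correlation). Astrocyte markers had 12 higher, 0 lower and 9 not passing of 21, the same adjusted over the list alone (mean 0.38, adjusted p = 3.51e-08, p = 0.00471 with an estimated correlation). Gja1, the connexin 43 of astrocytes, rose by 0.80 (SE 0.05), Glul, glutamine synthetase, by 0.75 (SE 0.05), and Gfap, the intermediate filament of astrocytes and radial stem cells, by 0.76 (SE 0.06). Oligodendrocyte lineage markers had 0 higher, 10 lower and 3 not passing of 13, the same adjusted over the list alone (mean -0.76, adjusted p = 8.11e-08, p = 0.00863 with an estimated correlation). The transcription factor Sox10 fell by 1.25 (SE 0.10). The precursor receptor Pdgfra fell by 0.96 (SE 0.06), a call lost with its most abundant transcript only (-1.98, adjusted p = 0.0941).

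All but 1 of the 22 genes of cholesterol synthesis were lower in the libraries labelled Dex, 21 also adjusted over the list alone (mean -0.65, adjusted p = 1.39e-16, p = 0.00316 with an estimated correlation). Mvd, mevalonate diphosphate decarboxylase, fell by 1.11 (SE 0.07) and the demethylase Cyp51 by 0.83 (SE 0.06). Of 54 genes of the G2/M phases, 0 were higher, 38 lower and 16 did not pass (1 higher and 44 lower adjusted over the list alone; mean -0.37, adjusted p = 8.12e-12, p = 0.0201 with an estimated correlation). Lbr, a receptor of the nuclear envelope, fell by 0.75 (SE 0.06) and Fam64a by 0.80 (SE 0.08). Of 43 genes of the G1/S phases, 31 were lower and 12 did not pass (34 lower adjusted over the list alone; mean -0.45, adjusted p = 3.84e-12). This call was lost with an adjusted p = 0.068 under an estimated correlation. Uhrf1, a DNA methylation maintenance factor, fell by 0.73 (SE 0.06) and the replication helicase subunit Mcm5 by 0.83 (SE 0.09).

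Fatty acid oxidation genes had 6 higher, 0 lower and 11 not passing of 17 in the libraries labelled Dex (7 higher adjusted over the list alone; mean 0.22, adjusted p = 1.13e-05, p = 0.0139 with an estimated correlation), led by Hmgcs2 (0.74), a ketogenic enzyme, and Pdk4 (0.47). Interferon response genes had 7 higher, 0 lower and 7 not passing of 14 (9 higher adjusted over the list alone; mean 0.32, adjusted p = 0.000133, p = 0.0256 with an estimated correlation), led by Ifit3 (0.90) and Rsad2 (0.56). Circadian clock genes had 8 higher, 0 lower and 8 not passing of 16 (9 higher and 1 lower adjusted over the list alone; mean 0.28, adjusted p = 8.68e-05, p = 0.0266 with an estimated correlation), led by the repressors Bhlhe41 (0.50) and Nr1d2 (0.45). Unfolded protein response genes had 0 higher, 11 lower and 5 not passing of 16, the same adjusted over the list alone (mean -0.38, adjusted p = 3.59e-05), with an adjusted p = 0.109 under an estimated correlation. Asns, asparagine synthetase, fell by 0.85 and the endoplasmic reticulum chaperone Hspa5 by 0.37. Cytosolic ribosomal protein genes had 34 lower and 6 not passing of 40 (35 lower adjusted over the list alone; mean -0.53, adjusted p = 3.84e-12), but an adjusted p = 0.259 under an estimated correlation. Rps2 fell by 0.81 and Rpl4 by 0.42, and the call for Rps2 was lost with its most abundant transcript only (-0.65, adjusted p = 0.0739). Untreated replicate 1 had the highest mean of these genes (8.39, against 8.11 and 8.01 in the other untreated libraries) and Dex replicate 1 the lowest (7.35, against 7.83 and 7.73).

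The libraries labelled BMP4 were compared with untreated in the same way, and because of the label check their changes are not credited to BMP4. In these libraries the glucocorticoid receptor targets had the highest mean rise of the fixed lists, astrocyte and fatty acid oxidation genes were also higher, and cholesterol synthesis, progenitor and cell cycle genes were lower. Sult1a1, a phenol sulfotransferase, went from 0.0922 ± 0.0799 FPKM (SD, n = 3) in untreated to 50.1 ± 2.29 (log2 fold change 5.55, SE 0.08, adjusted p = 3.18e-12). Lcn2, lipocalin 2, went from 0.244 ± 0.292 to 67.4 ± 6.00 FPKM (5.80, SE 0.14, adjusted p = 2.06e-10). Fam107a, an actin-associated protein, went from 0.320 ± 0.00991 to 71.8 ± 2.07 FPKM (5.79, SE 0.05, adjusted p = 4.18e-14). Ngfr, the low-affinity neurotrophin receptor, went from 9.71 ± 0.976 to 0.990 ± 0.0716 FPKM (-2.42, SE 0.09, adjusted p = 6e-09). In mm10 Sult1a1 (ENSMUSG00000030711) lies on chromosome 7 from 126672865 to 126676432, Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32384633 to 32388252, Fam107a (ENSMUSG00000021750) on chromosome 14 from 8296274 to 8318023 and Ngfr (ENSMUSG00000000120) on chromosome 11 from 95568818 to 95587735.

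Of the 13804 genes tested, 4423 changed in the libraries labelled BMP4, 1308 higher and 3115 lower. At least a 2-fold change was seen for 329, 239 higher and 90 lower (585 with a pseudocount of 0.1 and 133 with 5). The median of all genes was -0.109 in this comparison, and under median-of-ratios scaling, which moved it to -0.009, 1895 were higher and 1697 lower. Changes of lists are therefore also given relative to that median. The other genes among the 8 largest rises were Hif3a, a hypoxia-inducible factor (4.49), the sodium-activated potassium channel Kcnt1 (4.48), Hmgcs2 (3.91), Gjb6, connexin 30 of astrocytes (3.90), and Fkbp5 (3.75). The other falls were those of Gucy1a3, a subunit of soluble guanylate cyclase (-2.15), St6gal2 (-1.81), Eepd1 (-1.67), the growth cone protein Gap43 (-1.60), Gas7 (-1.55), Igfbp4 (-1.53) and Tead2 (-1.44). Adjusted p for these 16 genes was at most 0.000191. That of Tead2 was 0.0818 with its most abundant transcript only (-1.57).

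Of 22 glucocorticoid receptor targets, 19 were higher, 1 lower and 2 did not pass in the libraries labelled BMP4, the same adjusted over the list alone (mean 1.80, relative to the median of all genes 1.91, adjusted p = 3.7e-25, p = 0.000326 with an estimated correlation). Sult1a1 and Fkbp5 had the smallest adjusted p. Of 13 BMP-SMAD targets, 4 were higher, 3 lower and 6 did not pass (4 and 4 adjusted over the list alone), with a mean of 0.00, a median of -0.09 and an adjusted p = 0.592. The mean turned to -0.03 after rescaling the libraries to the same sum. Smad9, a receptor-regulated SMAD, rose by 1.41 (SE 0.07), while Bmper, a secreted modulator of BMP ligands, fell by 0.80 (SE 0.06). Id2 (0.26, adjusted p = 0.0316) and Id3 (-0.33, adjusted p = 0.0356) passed the test, but leaving out any 1 of BMP4 replicates 1, 2 or 3 ended both calls, with adjusted p of 0.111, 0.0568 and 0.0563 for Id2 and 0.0513, 0.101 and 0.0965 for Id3. Without untreated replicates 2 and 3 in turn, Id2 had 0.117 and 0.0738, and without untreated replicates 1 and 2 Id3 had 0.103 and 0.0558.

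Astrocyte markers had 13 higher, 5 lower and 3 not passing of 21 in the libraries labelled BMP4 (14 and 5 adjusted over the list alone; mean 0.56, relative 0.67, adjusted p = 7.95e-08, p = 0.00407 with an estimated correlation). Aldoc, the aldolase of astrocytes, rose by 2.22 (SE 0.06), Glul by 1.40 (SE 0.05) and Cbs, cystathionine beta-synthase, by 1.33 (SE 0.05). Quiescence genes had 9 higher, 4 lower and 10 not passing of 23 (9 and 5 adjusted over the list alone; mean 0.37, relative 0.48, adjusted p = 0.00014, p = 0.0165 with an estimated correlation), and Sparcl1 rose by 1.44 (SE 0.05). Genes of activated stem cells and progenitors had 0 higher, 13 lower and 8 not passing of 21 (1 higher and 15 lower adjusted over the list alone; mean -0.31, relative -0.20, adjusted p = 0.00448, p = 0.0452 with an estimated correlation). Mycn fell by 1.13 (SE 0.11), Sox11 by 0.49 (SE 0.06) and Ascl1 by 0.46 (SE 0.06).

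Each of the 22 genes of cholesterol synthesis was lower in the libraries labelled BMP4, also adjusted over the list alone (mean -0.78, relative -0.67, adjusted p = 4.28e-15, p = 0.00246 with an estimated correlation). Hmgcs1, the synthase at the start of the mevalonate pathway, fell by 1.12 (SE 0.05). Dhcr7, the last enzyme of the pathway, fell by 1.02 over its summed transcripts, but its most abundant transcript had 0.88 (adjusted p = 0.67). G2/M genes had 0 higher, 50 lower and 4 not passing of 54 (52 lower adjusted over the list alone; mean -0.56, relative -0.45, adjusted p = 6.18e-16, p = 0.0108 with an estimated correlation). The spindle motor Kif11 fell by 0.85 (SE 0.06) and Tmpo by 0.66 (SE 0.05). G1/S genes had 1 higher, 35 lower and 7 not passing of 43 (1 and 37 adjusted over the list alone; mean -0.50, relative -0.39, adjusted p = 1.24e-09), with an adjusted p = 0.123 under an estimated correlation. Uhrf1 fell by 0.73 and Mcm5 by 0.84.

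Fatty acid oxidation genes had 8 higher, 0 lower and 9 not passing of 17 in the libraries labelled BMP4 (8 and 1 adjusted over the list alone; mean 0.45, relative 0.56, adjusted p = 5.55e-07, p = 0.00943 with an estimated correlation), led by Hmgcs2 (3.91) and Pdk4 (0.77). Feedback genes of FGF-ERK signalling had 7 higher, 3 lower and 8 not passing of 18 (9 and 4 adjusted over the list alone; mean 0.14, relative 0.25, adjusted p = 0.00296, p = 0.0452 with an estimated correlation). Dusp6, a phosphatase of ERK, rose by 0.83 (SE 0.06) and Spred1 by 0.53 (SE 0.05). Extracellular matrix genes had 10 higher, 4 lower and 9 not passing of 23, the same adjusted over the list alone (mean 0.14, relative 0.25, adjusted p = 0.00136), with an adjusted p = 0.46 under an estimated correlation. Over the members with a mean FPKM of at least 5 their mean was -0.04 (adjusted p = 0.333). Sparc rose by 0.77 and tenascin C (Tnc) fell by 1.01. The call for Tnc was lost with its most abundant transcript only (-0.93, adjusted p = 0.0999). Ribosomal protein genes had 0 higher, 24 lower and 16 not passing of 40 (26 lower adjusted over the list alone; mean -0.37, relative -0.26, adjusted p = 0.00014), with an adjusted p = 0.63 under an estimated correlation, led by Rpl4 (-0.42) and Rpl10 (-0.49).

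The combination of Dex and BMP4 raised glucocorticoid targets, BMP targets and astrocyte genes together and lowered progenitor, cholesterol and cell cycle genes. This comparison with untreated does not depend on which single-treatment label is right. Fam107a reached 138 ± 0.687 FPKM (SD, n = 3) against 0.320 ± 0.00991 in untreated (log2 fold change 6.72, SE 0.05, adjusted p = 7.92e-15). Nrarp, a feedback inhibitor of Notch signalling, went from 34.0 ± 2.36 to 2.84 ± 0.725 FPKM (-3.20, SE 0.13, adjusted p = 6.25e-09), and the Notch ligand Dll3 from 23.2 ± 1.31 to 3.78 ± 0.695 (-2.35, SE 0.10, adjusted p = 9.24e-09). Fdps, farnesyl diphosphate synthase, went from 115 ± 11.9 to 21.01 ± 0.690 FPKM (-2.40, SE 0.10, adjusted p = 6.25e-09). In mm10 Nrarp (ENSMUSG00000078202) lies on chromosome 2 from 25180758 to 25183339, Dll3 (ENSMUSG00000003436) on chromosome 7 from 28293553 to 28302238 and Fdps (ENSMUSG00000059743) on chromosome 3 from 89093588 to 89101959.

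Of the 13804 genes tested, 7069 changed in the combination, 2186 higher and 4883 lower. At least a 2-fold change was seen for 1013, 464 higher and 549 lower (1587 with a pseudocount of 0.1 and 415 with 5). The median of all genes was -0.142, and under median-of-ratios scaling, which moved it to 0.007, 3291 were higher and 3154 lower. The other genes among the largest rises were Sult1a1 (6.08), Hmgcs2 (4.94), Lcn2 (4.91), Kcnt1 (4.89), Hif3a (4.59), Gjb6 (4.53) and Fkbp5 (4.15). The other falls were those of Nkain1 (-2.38), Mvd (-2.25), the cyclin-dependent kinase inhibitor Cdkn1c (-2.24), St6gal2 (-2.23) and Sncaip (-2.68). Adjusted p was at most 1.47e-06 for these 16 genes. Of these, Cdkn1c also stands in the quiescence list below and goes against the mean of that list. The call for Sncaip, which encodes synphilin 1, was lost with its most abundant transcript only (-1.47, adjusted p = 0.283).

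Of 22 glucocorticoid receptor targets, 21 were higher, 1 lower and 0 did not pass in the combination, the same adjusted over the list alone (mean 2.11, relative 2.25, adjusted p = 9.13e-20, p = 0.000799 with an estimated correlation). Of 13 BMP-SMAD targets, 9 were higher, 3 lower and 1 did not pass, the same adjusted over the list alone (mean 0.91, relative 1.05, adjusted p = 1.35e-05, p = 0.0184 with an estimated correlation). Smad9 rose by 2.50 (SE 0.07), Atoh8 by 2.57 (SE 0.11) and Id4 by 1.47 (SE 0.07). Astrocyte markers had 17 higher, 3 lower and 1 not passing of 21, the same adjusted over the list alone (mean 1.01, relative 1.16, adjusted p = 7.65e-12, p = 0.00133 with an estimated correlation). Aldoc rose by 2.88 (SE 0.06) and Glul by 1.91 (SE 0.05). Quiescence genes had 14 higher, 3 lower and 6 not passing of 23 (14 and 4 adjusted over the list alone; mean 0.65, relative 0.79, adjusted p = 3.72e-07, p = 0.00506 with an estimated correlation), and Sparcl1 rose by 2.45 (SE 0.05). Fatty acid oxidation genes had 11 higher, 0 lower and 6 not passing of 17 (11 and 1 adjusted over the list alone; mean 0.60, relative 0.75, adjusted p = 2.41e-06, p = 0.0111 with an estimated correlation), led by Hmgcs2 (4.94) and Pdk4 (1.31).

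**Figure D2:**
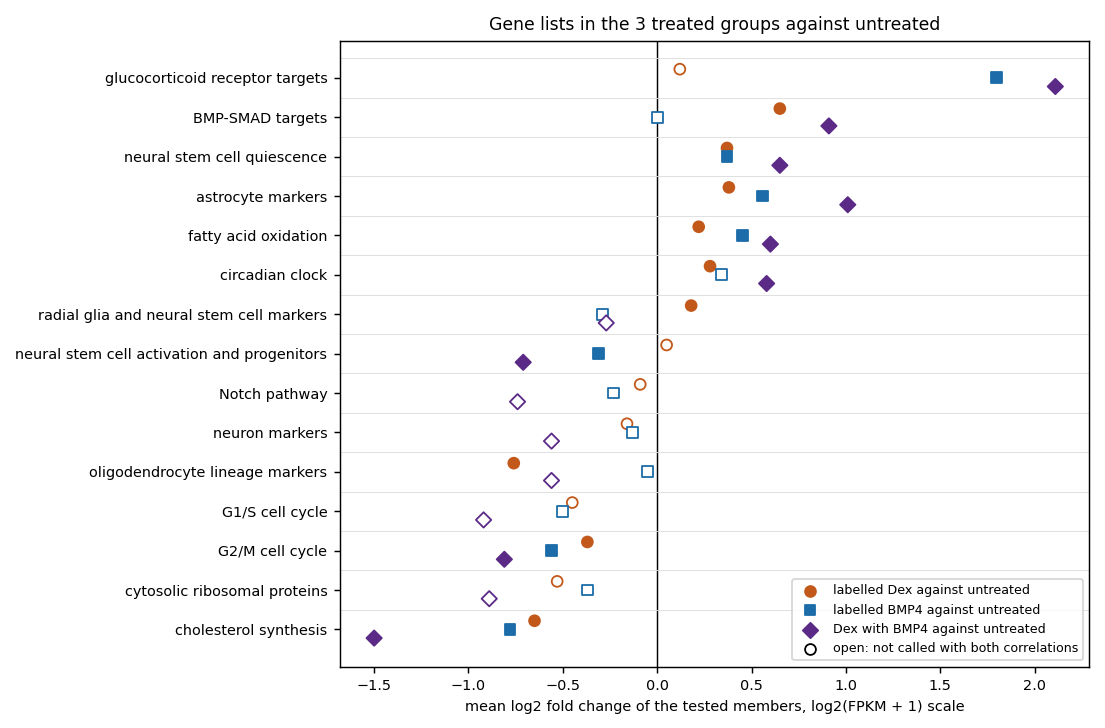
Mean log2 fold change against untreated of the tested members of 15 gene lists (horizontal axis, log2(FPKM + 1) scale) in the 3 treated groups; filled symbols mark lists with adjusted p under 0.05 both with the preset and with an estimated correlation, open symbols the others. Cholesterol synthesis had the lowest mean in the combination, -1.5, and glucocorticoid receptor targets the highest, 2.11.

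Genes of activated stem cells and progenitors had 2 higher, 16 lower and 3 not passing of 21 in the combination, the same adjusted over the list alone (mean -0.71, relative -0.57, adjusted p = 0.000357, p = 0.0166 with an estimated correlation). The transcription factors Sox11 and Sox4, active in newborn neurons, were lower (-1.15, SE 0.06, and -1.27, SE 0.08). Notch pathway genes had 2 higher, 11 lower and 4 not passing of 17, the same adjusted over the list alone (mean -0.74, relative -0.59, adjusted p = 0.0431), with an adjusted p = 0.174 under an estimated correlation. The Notch effector Hey1 fell by 0.90 (SE 0.06). Neuron markers had 1 higher, 8 lower and 2 not passing of 11 (1 and 9 adjusted over the list alone; mean -0.56, relative -0.42, adjusted p = 0.044), with an adjusted p = 0.11 under an estimated correlation. Gad1, a GABA-synthesizing enzyme, fell by 1.15 (SE 0.09). The RNA-binding protein gene Elavl4 fell by 1.01 over its summed transcripts, but its most abundant transcript had 0.03 (adjusted p = 0.946). Oligodendrocyte lineage markers had 1 higher, 9 lower and 3 not passing of 13, the same adjusted over the list alone (mean -0.56, relative -0.42, adjusted p = 0.0407), with an adjusted p = 0.174 under an estimated correlation. Gpr17 (-2.18) and the transcription factor Olig2 (-1.0) led the list. Leaving out a single library ended these calls. Without untreated replicates 2 and 3 and combination replicate 2 in turn, the adjusted p was 0.0516, 0.0659 and 0.0539 for the Notch list and 0.0516, 0.061 and 0.0568 for the neuron list. For the oligodendrocyte list it was 0.0572 without untreated replicate 3. Over the members with a mean FPKM of at least 5 the Notch, neuron and oligodendrocyte lists had 0.135, 0.34 and 0.0993, with the most abundant transcript 0.0649, 0.0763 and 0.156, and with only the groups compared in the model 0.055, 0.0578 and 0.0578.

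Cholesterol synthesis genes had 0 higher, 21 lower and 1 not passing of 22 in the combination (22 lower adjusted over the list alone; mean -1.5, relative -1.36, adjusted p = 3.17e-14, p = 0.00194 with an estimated correlation), led by Hmgcs1 (-2.07, SE 0.05), Dhcr7 (-1.88, SE 0.06) and Cyp51 (-1.86, SE 0.06). The call for Dhcr7 was lost with its most abundant transcript only (-0.02, adjusted p = 0.989). G2/M genes had 1 higher, 52 lower and 1 not passing of 54, the same adjusted over the list alone (mean -0.81, relative -0.67, adjusted p = 8.83e-14, p = 0.0145 with an estimated correlation), led by Tmpo (-1.04) and Kif11 (-1.29). G1/S genes had 1 higher and 42 lower of 43, the same adjusted over the list alone (mean -0.92, relative -0.78, adjusted p = 7.65e-12), with an adjusted p = 0.0803 under an estimated correlation. Uhrf1 (-1.57) and the replication helicase subunit Mcm2 (-1.41) led the list. Ribosomal protein genes had 0 higher, 38 lower and 2 not passing of 40, the same adjusted over the list alone (mean -0.89, relative -0.75, adjusted p = 1.41e-09), with an adjusted p = 0.33 under an estimated correlation. Rpl4 fell by 0.92 and Rpl10 by 1.06, and reads of such genes can be shared with their pseudogenes.

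The responses of the single treatments overlapped. Of the genes called against untreated in both, 366 were higher in both, where 125 would fall together by chance from the counts, 1229 were lower in both, where 504 would, and 328 changed in opposite directions, where 509 would. The opposite ones were 215 without untreated replicate 2 and 500 with array weights. Among the opposite ones, 221 were higher in the libraries labelled Dex and lower in those labelled BMP4, Gas7 among them, and 107 were the reverse. At 2-fold or more, 5 were higher in both, where 1.2 would fall together by chance from the counts, 8 lower in both, where 0.5 would, and 8 opposite, where 1.7 would. The fold changes had a Pearson r of 0.307 across genes, which are not independent replicates, and a covariance of 0.0401. Both comparisons share the 3 untreated libraries. In 20 simulations all libraries, the shared controls included, were redrawn without any change, with genes independent of each other. They gave a median r of 0.502 and a median covariance of 0.0106. Deviations that many genes of a real library share are absent from them. The observed covariance exceeded the simulated one by 0.0295, which for that reason does not measure a shared response. The controls were too few to be split, so part of the overlap cannot be separated from the shared controls. Under median-of-ratios scaling 576 were higher in both and 647 lower in both.

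The comparison of the libraries labelled Dex with those labelled BMP4 asked how the treatments differ, and its sign rests on the labels. The libraries labelled BMP4 had more transcripts of glucocorticoid receptor targets and of the oligodendrocyte lineage, and those labelled Dex had more of BMP targets, radial glia and progenitors. Against untreated, oligodendrocyte markers had a mean of -0.76 in labelled Dex and -0.05 in labelled BMP4, so this difference was mostly a fall in labelled Dex. Progenitor genes had 0.05 in labelled Dex and -0.31 in labelled BMP4, mostly a fall in labelled BMP4. Mfsd2a had 2.13 ± 0.0782 FPKM (SD, n = 3) in the libraries labelled Dex and 91.3 ± 1.89 in those labelled BMP4 (-4.88, SE 0.07, adjusted p = 2.2e-12). Gas7 had 66.1 ± 2.17 and 5.73 ± 0.188 FPKM (3.32, SE 0.16, adjusted p = 5.31e-08), and Gucy1a3 had 16.6 ± 0.365 and 1.16 ± 0.0275 (3.03, SE 0.08, adjusted p = 4.4e-10). In mm10 Mfsd2a (ENSMUSG00000028655) lies on chromosome 4 from 122946850 to 122961188, Gas7 (ENSMUSG00000033066) on chromosome 11 from 67455437 to 67688990 and Gucy1a3 (ENSMUSG00000033910) on chromosome 3 from 82092427 to 82145789.

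Between the single treatments 4175 of 13804 genes differed, 2500 higher and 1675 lower in the libraries labelled Dex, and 463 by at least 2-fold, 215 higher and 248 lower (784 with a pseudocount of 0.1 and 165 with 5). Under median-of-ratios scaling 1847 were higher and 2090 lower, and after rescaling the libraries to the same sum 3908 and 1141. The other genes among the largest differences toward labelled Dex were Ngfr (2.71), Efemp1 (2.66), Islr (2.48), the small GTPase Gem (2.29), the laminin receptor subunit Itga6 (2.28) and Eepd1 (2.22). Toward labelled BMP4 they were Lcn2 (-5.98), Fam107a (-5.80), Sult1a1 (-5.35), Fkbp5 (-4.32), Hif3a (-4.21), Gjb6 (-3.69) and Kcnt1 (-3.51). Adjusted p for these 16 genes ranged from 4.06e-14 to 2.66e-07.

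Of 22 glucocorticoid receptor targets, 1 was higher, 19 lower and 2 did not pass in labelled Dex against labelled BMP4 libraries, the same adjusted over the list alone (mean -1.68, adjusted p = 4.54e-18, p = 0.00111 with an estimated correlation). BMP-SMAD targets had 9 higher, 1 lower and 3 not passing of 13, the same adjusted over the list alone (mean 0.64, adjusted p = 0.000161, p = 0.045 with an estimated correlation), led by Bmper (1.56) and Id3 (1.43). Radial glia and stem cell markers had 12 higher, 1 lower and 3 not passing of 16 (12 and 2 adjusted over the list alone; mean 0.47, adjusted p = 0.000161, p = 0.0185 with an estimated correlation), led by Tnc (2.00) and Sox21 (1.09). Progenitor genes had 12 higher, 2 lower and 7 not passing of 21 (14 and 2 adjusted over the list alone; mean 0.37, adjusted p = 0.00178, p = 0.0399 with an estimated correlation), led by Mycn (1.93) and Ascl1 (0.90). Regulators of Ascl1 had 8 higher, 0 lower and 7 not passing of 15 (9 higher adjusted over the list alone; mean 0.52, adjusted p = 0.000231, p = 0.0367 with an estimated correlation), led by Id3 and Id4 (0.77). Oligodendrocyte lineage markers had 0 higher, 11 lower and 2 not passing of 13, the same adjusted over the list alone (mean -0.71, adjusted p = 6.52e-09, p = 0.0109 with an estimated correlation), led by the proteoglycan Cspg4 (-1.74) and Gpr17 (-1.45). Interferon response genes had 11 higher, 0 lower and 3 not passing of 14, the same adjusted over the list alone (mean 0.48, adjusted p = 0.00139), with an adjusted p = 0.0586 under an estimated correlation. Ifit3 differed by 1.46, and Stat1 by 0.58 over its summed transcripts but by -0.02 in its most abundant one (adjusted p = 0.951). Unfolded protein response genes had 0 higher, 10 lower and 6 not passing of 16 (11 lower adjusted over the list alone; mean -0.39, adjusted p = 3.14e-06), with an adjusted p = 0.0963 under an estimated correlation, led by Asns (-1.27) and Hspa5 (-0.39).

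The combination was compared with each single treatment to ask what the second factor added. Against the libraries labelled BMP4, BMP targets, glucocorticoid receptor targets and astrocyte genes were higher in the combination and oligodendrocyte and cholesterol genes lower. BMP-SMAD targets had 11 higher, 1 lower and 1 not passing of 13, the same adjusted over the list alone (mean 0.91, adjusted p = 7.65e-12, p = 0.00357 with an estimated correlation), led by Id4 (1.56) and Atoh8 (2.02). Glucocorticoid receptor targets had 10 higher, 1 lower and 11 not passing of 22 (13 and 1 adjusted over the list alone; mean 0.30, adjusted p = 1.67e-06, p = 0.0111 with an estimated correlation). Astrocyte markers had 15 higher, 0 lower and 6 not passing of 21 (16 and 1 adjusted over the list alone; mean 0.45, adjusted p = 7.06e-12, p = 0.00128 with an estimated correlation), led by Gfap (1.39) and Gja1 (0.66). Oligodendrocyte lineage markers had 0 higher, 10 lower and 3 not passing of 13, the same adjusted over the list alone (mean -0.52, adjusted p = 7.2e-07, p = 0.0111 with an estimated correlation), led by Gpr17 (-1.27) and Olig2 (-0.71). Cholesterol synthesis genes had 0 higher, 20 lower and 2 not passing of 22 (21 lower adjusted over the list alone; mean -0.72, adjusted p = 9.26e-19, p = 0.00128 with an estimated correlation), led by Hmgcs1 (-0.95) and Idi1 (-1.07). In all 2749 of 13804 genes differed, 1101 higher and 1648 lower, and 168 by at least 2-fold, 87 higher and 81 lower (379 with a pseudocount of 0.1 and 45 with 5). Under median-of-ratios scaling 1478 were higher and 1219 lower.

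Against the libraries labelled Dex, glucocorticoid receptor targets and astrocyte genes were higher in the combination and progenitor and cholesterol genes lower. Glucocorticoid receptor targets had 19 higher, 1 lower and 2 not passing of 22, the same adjusted over the list alone (mean 1.98, relative 2.1, adjusted p = 2.74e-23, p = 0.000435 with an estimated correlation), led by Sult1a1 (5.88) and Fkbp5 (4.72). Astrocyte markers had 13 higher, 3 lower and 5 not passing of 21 (13 and 4 adjusted over the list alone; mean 0.64, relative 0.75, adjusted p = 8.19e-08, p = 0.00368 with an estimated correlation), led by Aldoc (2.60) and Cbs (1.64). Progenitor genes had 1 higher, 18 lower and 2 not passing of 21, the same adjusted over the list alone (mean -0.77, relative -0.65, adjusted p = 4.05e-07, p = 0.00368 with an estimated correlation), led by Mycn (-1.95) and Sox11 (-1.02). Cholesterol synthesis genes had 0 higher, 21 lower and 1 not passing of 22, the same adjusted over the list alone (mean -0.86, relative -0.74, adjusted p = 5.49e-13, p = 0.00368 with an estimated correlation), led by Hmgcs1 (-1.38) and Idi1 (-1.12). In all 5068 genes differed, 1573 higher and 3495 lower, and 530 by at least 2-fold, 321 higher and 209 lower (914 with a pseudocount of 0.1 and 225 with 5). The median of all genes was -0.113, and under median-of-ratios scaling 2287 were higher and 2067 lower.

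The interaction asked whether the combination differs from the sum of the single changes on the log2 scale, and exchanging the single-treatment labels leaves it the same. The lists of progenitor and Notch genes were on average lower in the combination than that sum. Dll1, a Notch ligand of committed progenitors, had 45.0 ± 3.76 FPKM (SD, n = 3) in untreated, 49.8 ± 7.09 in labelled Dex, 30.9 ± 4.32 in labelled BMP4 and 13.1 ± 0.962 in combination libraries (interaction -1.31, SE 0.17, adjusted p = 0.00257). Pcp4, a calmodulin-binding protein of neurons, had 0.975 ± 0.278, 2.90 ± 0.443, 1.69 ± 0.480 and 16.8 ± 0.745 FPKM in the same order (1.75, SE 0.20, adjusted p = 0.00141). In mm10 Dll1 (ENSMUSG00000014773) lies on chromosome 17 from 15367354 to 15376872 and Pcp4 (ENSMUSG00000090223) on chromosome 16 from 96467606 to 96525793.

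An interaction was called for 238 of 13804 genes, 116 positive and 122 negative, and 43 reached 2-fold, 19 positive and 24 negative (57 with a pseudocount of 0.1 and 7 with 5). The other genes named by the rule were Mpp3 (1.68), Kpna1 (1.64) and Cnr1, the cannabinoid receptor 1 (1.5), with positive values, and Sncaip (-1.44), Lypd1 (-1.34) and the glutamine transporter Slc38a1 (-1.28), with negative ones. Their adjusted p ranged from 3.93e-05 to 0.0123. With the most abundant transcript only the calls were lost for Sncaip (-0.60, adjusted p = 0.926), Slc38a1 (-1.0, adjusted p = 0.195) and Lypd1 (-1.06, adjusted p = 0.071). The count depended on single libraries. It was 154 without untreated replicate 2, 153 and 113 without Dex replicates 2 and 3, 136, 131 and 149 without BMP4 replicates 1, 2 and 3, and 123 and 120 without combination replicates 2 and 3. It also moved with no filter (133), array weights (561), the most abundant transcript (143) and the length trend removed (379).

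Progenitor genes had an interaction in 0 positive and 7 negative of 21 members, with 14 not passing (1 and 10 adjusted over the list alone; mean -0.46, adjusted p = 1.11e-09, p = 0.00355 with an estimated correlation). Neurog2, a proneural transcription factor, had -1.15 (SE 0.14) and Sox4 -0.91 (SE 0.11). Notch pathway genes had 0 positive and 5 negative of 17, with 12 not passing (1 and 6 adjusted over the list alone; mean -0.42, adjusted p = 1.01e-05, p = 0.0378 with an estimated correlation). Besides Dll1, Mfng, a glycosyltransferase of Notch, had -1.53 (SE 0.20) and the effector Hes5 -1.15 (SE 0.18). Neuron markers were negative on average, with 0 positive, 0 negative and 11 not passing of 11 (0 and 2 adjusted over the list alone; mean -0.27, adjusted p = 0.0127, p = 0.108 with an estimated correlation). Radial glia and neural stem cell markers had 1 positive, 1 negative and 14 not passing of 16 (1 and 3 adjusted over the list alone; mean -0.17, adjusted p = 0.031, p = 0.131 with an estimated correlation). Oligodendrocyte lineage markers had 3 positive, 0 negative and 10 not passing of 13 (5 and 1 adjusted over the list alone; mean 0.24, adjusted p = 0.0127, p = 0.144 with an estimated correlation). Glucocorticoid receptor targets had 3 positive, 0 negative and 19 not passing of 22 (6 and 1 adjusted over the list alone; mean 0.18, adjusted p = 0.00224), with an adjusted p = 0.108 under an estimated correlation, led by Fkbp5 (0.97) and Sgk1 (1.11). The call for Sgk1 was lost with its most abundant transcript only (0.30, adjusted p = 0.92). BMP-SMAD targets had 2 positive, 1 negative and 10 not passing of 13 (7 and 2 adjusted over the list alone; mean 0.26, adjusted p = 0.00511), with an adjusted p = 0.131 under an estimated correlation, led by Id4 (0.88, adjusted p = 0.000748). Smad9 followed (0.57, adjusted p = 0.0189) but was not called without Dex replicate 3 (0.056), BMP4 replicate 1 (0.0574), BMP4 replicate 2 (0.0584), combination replicate 1 (0.0534) or combination replicate 3 (0.057). Its call was also lost with a pseudocount of 0.1 (0.109), after rescaling to the same sum (0.169) and with limma-voom (0.0833).

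Ascl1, a proneural transcription factor of activated stem cells and progenitors (ENSMUSG00000020052, mm10 chromosome 10 from 87490819 to 87493660), had 67.9 ± 3.24 FPKM (SD, n = 3) in untreated, 92.0 ± 6.26 in labelled Dex, 49.0 ± 2.23 in labelled BMP4 and 64.3 ± 1.81 in combination libraries. It rose by 0.43 in the libraries labelled Dex (SE 0.06, adjusted p = 0.000724) and fell by 0.46 in those labelled BMP4 (SE 0.06, adjusted p = 0.000252). The difference between the single treatments was 0.90 (SE 0.06, adjusted p = 1.2e-06). In the combination the difference from untreated was -0.08 (SE 0.06, adjusted p = 0.348) and did not pass. The combination lay 0.39 above the libraries labelled BMP4 (adjusted p = 0.00148) and fell by 0.51 against those labelled Dex (adjusted p = 9.26e-05). The interaction of Ascl1 was -0.05 (SE 0.09, adjusted p = 0.895), and relative to the median of all genes the changes were 0.47, -0.35 and 0.07 in the 3 treated groups.

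**Figure D3:**
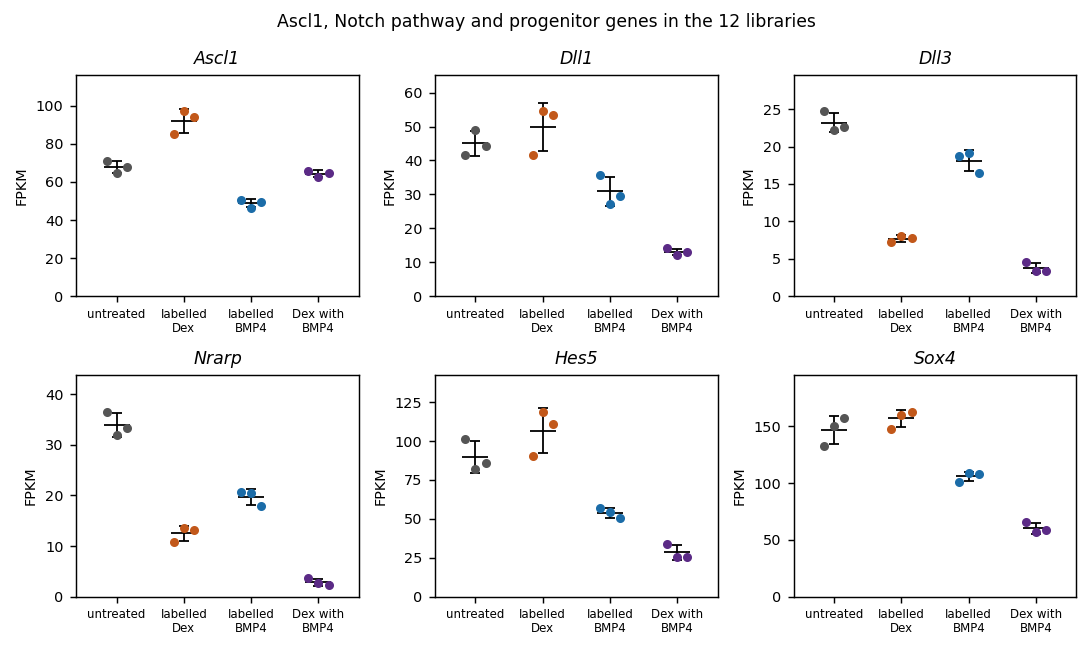
Expression in FPKM of Ascl1 and of 5 Notch pathway and progenitor genes in each of the 12 libraries, by labelled group; points are libraries, and bars show the mean and SD of the 3 libraries of a group. Dll1, Dll3, Nrarp, Hes5 and Sox4 are lowest in the combination, while Ascl1 there is within 0.08 of untreated on the log2 scale.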

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

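The tests that weigh the progenitor and Notch pattern were chosen only after the result was seen, while the interaction test itself was fixed before. A difference between groups brought these results here, as the response to the combination differed from the sum of the responses to the single treatments by the interaction test. This was so for 238 genes. Among genes with a mean of at least 5 FPKM in some group, the largest values were 1.75 for Pcp4, 1.68 for Mpp3, 1.64 for Kpna1 and 1.5 for Cnr1, and -1.44 for Sncaip, -1.34 for Lypd1, -1.31 for Dll1 and -1.28 for Slc38a1. Kpna1 varied widely between the replicates labelled Dex (15.3 ± 6.47 FPKM, SD, n = 3). The mean interaction was -0.46 over the list of activated stem cells and progenitors and -0.42 over the Notch pathway list.

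The progenitor and Notch genes were weighed further, since 7 of 21 and 5 of 17 members, Dll1, Neurog2, Sox4 and Hes5 among them, fell in the combination below what the single treatments add up to. An effect of the log scale and pseudocount could give such values, but on linear FPKM relative to each gene's mean, over all tested members, the mean interaction was -0.32 (SE 0.032) for the 21 progenitor genes and -0.20 (SE 0.028) for the 17 Notch genes. A single library could also carry the pattern, but the progenitor list kept its call in 12 of 12 fits that each left out a library, with means from -0.48 to -0.43. The Notch list was not weighed in this way. Among its 5 members with a call, Hey1 (-0.47, adjusted p = 0.0226) lost it in several of these fits, with adjusted p from 0.0509 to 0.0716. Fewer cycling cells could lower progenitor genes, but the mean interaction of the G2/M list was 0.12 (SE 0.042), so that the cell cycle genes did not fall below the sum. A shift in cell types was not tested and stays open, with a mean interaction of -0.27 for neuron and 0.24 for oligodendrocyte lineage markers, as does joint action of Dex and BMP4 on these genes.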

How the results depend on the processing

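The settings that leave out the libraries that stand apart or remove the length trend, and the overlap and label check under the alternatives of the other results, were chosen only after the data were seen. Of the values under other settings, 138 counts of changed genes stayed within 1.5 times the main count and 14 did not. Of the named gene results 5803 were the same, 79 weaker, 14 stronger and 5 reversed, and of the list results 4514, 193, 90 and 10. The overlap was the same in 61 and moved in 11, and the label check in 15 and 7. Depth in reads is unknown, so what it limits was not measured. Without single libraries the counts ranged from 2586 to 3539 for labelled Dex, 3337 to 4775 for labelled BMP4 and 6228 to 7006 for the combination against untreated. They ranged from 3176 to 3641 for labelled Dex against labelled BMP4, 4157 to 4581 and 1863 to 2129 for the combination against labelled Dex and labelled BMP4, and 113 to 332 for the interaction. The overlap ranged from 286 to 374 higher in both, 917 to 1227 lower in both and 215 to 363 opposite, and the label check from -2.23 to -2.15 and from 0.86 to 0.94.

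The count of the interaction, 238, moved to 133 with no filter, where more genes are tested, and to 154 with the replicate block. It was 561 with array weights, 143 with the most abundant transcript and 379 with the length trend removed. The count for labelled Dex against untreated moved to 1735 with only the groups compared. Fewer libraries alone do not account for it. The same setting raised the counts to 4338 for labelled Dex against labelled BMP4, and to 3595 and 5258 for the combination against labelled BMP4 and labelled Dex. Median differences between replicates reached 0.189 in untreated and 0.124 in labelled Dex, against at most 0.089 in the other groups. The main model shares its estimate of the spread across all groups. Genes lower in both single treatments were 811 with no filter, 647 under median-of-ratios scaling, 765 under quantile normalization and 817 with the most abundant transcript. Genes higher in both were 576 under median-of-ratios scaling and 683 with the length trend removed, and opposite ones 500 with array weights and 215 without untreated replicate 2. At 2-fold or more the overlap was 5 higher in both, 8 lower in both and 8 opposite, by the construction of that threshold. The label check gave -2.54 and 1.04 with a pseudocount of 0.1, -1.63 and 0.81 with 5, -2.27 and 1.06 after rescaling to the same sum, and -2.38 for the glucocorticoid targets with the most abundant transcript, in each case with the same sign. Other than where said, the cause was not tested.

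By fry these lists reversed the direction of camera: Notch in labelled Dex (-0.09), oligodendrocyte lineage in labelled BMP4 (-0.05) and immediate early genes in the combination against untreated (-0.16) and against labelled Dex (-0.08). The 2 tests ask different questions, since camera compares a list with the other genes and fry with no change. Relative to the median of all genes, these means were -0.05, 0.06, -0.02 and 0.03 in the same order. Quantile normalization reversed the mitochondrially encoded genes in the combination against untreated (-0.04), in labelled Dex against labelled BMP4 (0.01) and in the combination against labelled Dex (-0.08). The ribosomal protein interaction, 0.01, turned to -0.24 without the libraries that stand apart, to -0.10 without untreated replicate 1 and to -0.13 without Dex replicate 1, and was 0.11 without Dex replicate 2. With the most abundant transcript Dhcr7 reversed in labelled Dex (1.07) and labelled BMP4 (0.88), and so did Kcnn2 (-0.58), Elavl4 in the combination (0.03) and Stat1 between the single treatments (-0.02). The cause was not tested. Without both libraries that stand apart the counts were 2571, 5207 and 7381 for labelled Dex, labelled BMP4 and the combination against untreated, 4533 for labelled Dex against labelled BMP4, 4007 and 5643 for the combination against labelled BMP4 and labelled Dex, and 355 for the interaction.

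With the replicate block the counts were 3259, 4221 and 6865 against untreated in the same order, 3938 for labelled Dex against labelled BMP4, 2558 and 4864 for the combination against labelled BMP4 and labelled Dex, and 154 for the interaction. The labels give only a number, and the residuals of the 18 pairs with the same number correlated from -0.197 to 0.266, with 4 over 0.1. These included all 3 pairs of untreated with labelled BMP4 (0.266, 0.117 and 0.156), while those of untreated with labelled Dex were -0.197, -0.109 and -0.022. The block is 1 factor across all 4 groups, and since not every pair was over 0.1, the libraries were not taken as paired. As a hint from the data and not from the design, 8 of 12 libraries correlated best with their own number. With the block the adjusted p was over 0.05 for Id2 (0.0546) and Id3 (0.0615) in labelled BMP4, for Psmb8 (0.0693) and the Notch list (0.0543) in the combination, and for the interaction of Hey1 (0.0508) and Smad9 (0.0514).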

Other observations

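Of the tests in this part, the label exchange was written down before the data were examined, and the tests of correct labels, of the ribosomal protein genes and of other groupings were chosen only after the results were seen. Circadian clock genes were higher in the combination, with 10 higher, 1 lower and 5 not passing of 16 (11 and 1 adjusted over the list alone; mean 0.58, adjusted p = 1.45e-05, p = 0.0184 with an estimated correlation), led by Npas2 (2.57) and Per1 (2.09), which is also a glucocorticoid target. In the libraries labelled BMP4 the list had 5 higher and 2 lower (mean 0.34, adjusted p = 0.00117), with an adjusted p = 0.0632 under an estimated correlation. Glycolysis genes had 8 higher and 1 lower of 18 in the combination (mean 0.33, adjusted p = 0.000443, p = 0.0926 with an estimated correlation), and 5 and 1 in labelled BMP4 (mean 0.22, adjusted p = 0.00136, p = 0.125 with an estimated correlation), led by Aldoc and the muscle-type phosphofructokinase Pfkm (1.26 and 0.80). In labelled Dex they had 4 and 3 (adjusted p = 0.704). Wnt pathway genes were split, with 6 higher and 7 lower of 16 in the combination (mean 0.01, median -0.18, adjusted p = 0.613), the receptor Fzd1 at 2.22 and the ligand Wnt7a at -1.39, 4 and 5 in labelled BMP4 (adjusted p = 0.592) and 4 and 4 in labelled Dex (adjusted p = 0.325). FGF-ERK feedback genes had 10 higher and 3 lower of 18 in the combination (mean 0.13, adjusted p = 0.00613, p = 0.0502 with an estimated correlation) and 4 and 5 in labelled Dex (adjusted p = 0.97).

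Radial glia and stem cell markers had 6 higher and 2 lower of 16 in labelled Dex (mean 0.18, adjusted p = 0.0022, p = 0.0256 with an estimated correlation), with Gfap at 0.76 and Nes, the intermediate filament nestin, at -0.92. In labelled BMP4 they had 2 higher and 8 lower (mean -0.29, adjusted p = 0.0476, p = 0.123 with an estimated correlation), a call lost without untreated replicate 2 (adjusted p = 0.0845), BMP4 replicate 1 (0.0578) or BMP4 replicate 3 (0.0574), under median-of-ratios scaling (0.051) and with the most abundant transcript (0.257), and in the combination 3 and 7 (adjusted p = 0.438). Regulators of Ascl1 had 5 higher and 0 lower of 15 in labelled Dex (mean 0.32, adjusted p = 0.00122, p = 0.0309 with an estimated correlation), led by Id1 and Id2, 1 and 5 in labelled BMP4 (adjusted p = 0.409) and 4 and 5 in the combination (mean 0.12, median -0.09, adjusted p = 0.304). CDK inhibitors had 1 higher and 4 lower of 8 in the combination (adjusted p = 0.58), with Cdkn1c at -2.24 and Cdkn1a at 0.59, and were not called in labelled Dex (adjusted p = 0.0889) or labelled BMP4 (adjusted p = 0.471). Steroid and BMP receptors had 2 higher of 12 in labelled Dex (mean 0.19, adjusted p = 0.0385, p = 0.303 with an estimated correlation), a call lost without untreated replicate 1 (adjusted p = 0.117) or Dex replicate 1 (0.0911) and with the length trend removed (0.19), with Bmpr1a at 0.65. They were not called in labelled BMP4 (adjusted p = 0.685) or the combination (adjusted p = 0.845), where the glucocorticoid receptor gene Nr3c1 had -0.81. Of the lists not called, progenitor genes in labelled Dex had 7 higher and 5 lower of 21 (adjusted p = 0.2), Notch genes 3 and 3 of 17 in labelled Dex (mean -0.09, median 0.02, adjusted p = 0.97) and 1 and 7 in labelled BMP4 (adjusted p = 0.283). Neuron markers had 2 and 5 of 11 in labelled Dex (adjusted p = 0.2) and 0 and 3 in labelled BMP4 (adjusted p = 0.951), and oligodendrocyte markers 3 and 6 of 13 in labelled BMP4 (adjusted p = 0.951).

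Mitochondrially encoded genes had 0 of 13 past the threshold in labelled Dex (adjusted p = 0.412), 4 higher in labelled BMP4 (mean 0.24, adjusted p = 0.000232, p = 0.46 with an estimated correlation) and 3 higher in the combination (mean 0.13, adjusted p = 0.0324, p = 0.572 with an estimated correlation). Extracellular matrix genes had 11 higher and 4 lower of 23 in the combination (mean 0.22, adjusted p = 0.00236, p = 0.398 with an estimated correlation) and were not called in labelled Dex (adjusted p = 0.97). Unfolded protein response genes had 5 and 3 of 16 in labelled BMP4 (adjusted p = 0.409) and 2 and 11 in the combination (adjusted p = 0.238). Interferon response genes had 1 and 3 of 14 in labelled BMP4 (adjusted p = 0.722) and 5 and 1 in the combination (adjusted p = 0.141). Antigen presentation genes had adjusted p of 0.278, 0.722 and 0.161 in labelled Dex, labelled BMP4 and the combination, with H2-T23 at 1.82 in the combination. Immediate early genes had 0.97, 0.583 and 0.855, with Jun at -1.35 and Junb at 1.2 in the combination, fibroblast and mesenchymal markers 0.452, 0.951 and 0.885, and ependymal markers 0.97, 0.0723 and 0.0745.

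An exchange of the labels Dex and BMP4 could account for the pattern of the label check. It predicts that glucocorticoid targets rise in the libraries labelled BMP4 and BMP targets in those labelled Dex, and the glucocorticoid mean differed by -2.19 (SE 0.049) between labelled Dex and labelled BMP4, with the BMP mean at 0.90 (SE 0.051). Correct labels predict a rise of glucocorticoid targets in labelled Dex. There the mean of the 4 genes differed from untreated by -0.36 (SE 0.05), against 2.11 (SE 0.024) in the combination. The 22 targets of the longer list had a mean of 0.12 in labelled Dex (adjusted p = 0.103 by camera, 0.0442 by fry), against 1.80 in labelled BMP4. They differed by -1.68 between labelled Dex and labelled BMP4, and lay 0.30 higher in the combination than in labelled BMP4. The BMP-SMAD list had a mean of 0.65 in labelled Dex and 0.00 in labelled BMP4. The 4-gene means and the means of both longer lists lie as an exchange predicts. The longer lists contain the 4 glucocorticoid targets and Id1, Id2 and Id3, so they are not independent of the 4-gene means. Whether such an exchange arose in the cultures, the libraries, the files or the labels was not tested. Under an exchange the fall of Ascl1 by 0.46 would belong to Dex and its rise by 0.43 to BMP4.

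The ribosomal protein genes were lower in all 3 treated groups as deposited, by -0.53 (SE 0.185), -0.37 (SE 0.12) and -0.89 (SE 0.115) in labelled Dex, labelled BMP4 and the combination. A trend with transcript length could lower them, since their median length was 857 bp against 2504 bp for all genes, but with the trend removed the smallest of the 3 falls was still -0.24 (SE 0.061). Untreated replicate 1, which had the highest mean, could carry the difference, but without it the smallest fall was -0.26 (SE 0.061). That fall was in labelled BMP4, where the median of all genes without this library was -0.122, so part of it is shared with other genes. Dex replicate 1, the lowest of its group (7.35, against 7.83 and 7.73), was kept in this test. Reads shared with pseudogenes were not tested and stay open, and the list was not called with an estimated correlation. The biological explanation, the treatments themselves, was left standing without a further test.

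Other groupings of the same libraries were counted as well. For each comparison of 3 against 3 libraries, 1 of 10 groupings, the real one, gave as many genes, which is too few groupings for a share under 0.05. The real counts were 3553, 4423, 7069, 4175, 2749 and 5068, and the highest of any other grouping was 1, 1, 0, 1, 1 and 1, in the order labelled Dex, labelled BMP4 and the combination against untreated, labelled Dex against labelled BMP4, and the combination against labelled BMP4 and against labelled Dex. Each other grouping mixes libraries of both real groups, which moves a real difference into the spread within groups. Low counts there are thus built in and cannot decide about chance. For the interaction, 5 of 100 groupings, the real one included, gave at least 238 genes, and the highest gave 2750. These groupings mix all libraries, so differences between the treatments enter them. The 4 other groupings lay close to the treatment contrasts themselves (alignment of at least 0.67, against a median of 0.33 for the rest). The grouping with 2502 genes was the contrast of libraries labelled with and without Dex itself (alignment -1). This count thus cannot decide about chance, which stays open for the number of genes with an interaction.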
